A study of Mus musculus with 4 samples.

How the data were processed

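Per the labels' protocols, RNA was extracted with Trizol from keratinocytes harvested before confluence, full-length cDNA was amplified, and libraries were made by tagmentation with a Nextera kit. The kit step named there does not state a strand, so a gene and its antisense partner cannot be told apart. Per the submitters' processing notes, TopHat, HTSeq and the mouse build mm10 were used, with no version or order. The annotation used is not given in the sources used here.

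The authors deposited 2 tables. In the first, expression is in FPKM for 4 libraries, and the tool that made it is not given in the sources used here. It had 24487 rows after 1 repeated header line was removed. The second is the authors' comparison of mutant with control, with 24062 rows. Per the file headers it holds a mean normalized signal over all samples, a log2 fold change with its standard error, a test score, and p-values with adjusted values, under column names like those of a DESeq2 results table. An adjusted p is given there for 11582 rows. The deposited log2 fold changes correlated with those of mutant over control FPKM at r = 0.821 across 11290 genes, which are not independent replicates. For some genes the deposited values lay much nearer 0, as for Krt10 (0.11 against 1.49) and Lce1e (1.17 against 2.73). For others, such as Lamb3 (-0.67 against -0.68), they were close.

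Samples were grouped by the genotype label. The columns of the deficient libraries are named mutant 1 and 2, while the labels use another code, so those columns were assigned to the Ovol2-deficient group and their numbers are those of the table. The files held no counts. The design fixed before the data were examined gave a count test for counts and limma for normalized values, with counts thought likely, and the limma branch was used. The libraries were compared first, and 5 to 13 of 11350 values were identical between any pair, so none was a copy of another.

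Rows with date-like symbols (27) were left out, since the gene names were lost. Rows sharing a symbol were summed, which left 23970 symbols. Genes with a mean FPKM of at least 1 over the 4 libraries were tested (11350), on log2(FPKM + 1), with limma 3.58.1 in R 4.3.3 (group as the only term, empirical Bayes with a variance trend, Benjamini-Hochberg adjustment, threshold 0.05). Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Means and SDs are of FPKM, with n = 2 per group. The median log2 fold change of all tested genes was -0.0014. Groups of 2 against 2 are separated by chance for 33.3% of genes, and 48.1% were separated. With 2 libraries per group, no permutation of libraries can give a small p, so the tests rest on the model.

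The 24 gene lists, with 688 members (681 found in the table), were written before the data were examined, as were the main alternatives. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. With 4 libraries the test at an estimated correlation has few degrees of freedom and could hardly pass a list. Members were also counted when adjusted over the list alone. The named genes followed a rule fixed at the same time. They were Ovol2 and 16 chosen genes, the 8 largest changes in each direction among called genes with a group mean FPKM of at least 5 and no overlap between the groups, and up to 2 called members per direction in each list. One gene that the rule names is not reported here. Coordinates are from GENCODE M21, on the same build as mm10.

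The model was tested on simulated data. With variances drawn from limma's fitted prior, 11350 genes and 200 of them changed, it recovered 33.0%, 87.1% and 99.5% of genes changed 1.5-fold, 2-fold and 4-fold over 20 simulations, with 5.25% of calls false and a mean of 0.1 calls when nothing was changed. With each gene's own estimated variance, 10.3% of calls were false, above the 5% aimed at, and a mean of 4 genes were called when nothing was changed. The list test found a planted shift of -0.5 in the G2 and M phase list in 20 of 20 simulations and called 2 of 440 tests of other lists. Genes were drawn independently there, while the estimated correlation within that list was 0.534 in the data. The simulation therefore does not check list calls where genes are correlated. For the gene test, variances drawn from limma's own prior meet the model's assumptions, so a false share near 5% was largely set in advance. Neither gene simulation checks shifts that many genes of a library share.

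Depth was not given. In the authors' deposited table the lowest mean normalized values take a few levels, as single reads divided by a size factor do, and these gave size factors of 0.931, 0.954, 1.11 and 1.01. With a mean normalized total of 13340000 they correspond to about 12400000 to 14800000 counted reads. The totals assume equal normalized totals in the libraries. No counting interval was computed.

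The alternatives were the replicate number as a block, quantile normalization, a pseudocount of 0.1, no filter, a 2-fold threshold and each library left out. After seeing the data, a filter at a mean FPKM of 5, a filter on all-zero genes only, median-ratio scaling, limma without the trend, and a fit without snoRNA, microRNA and Amd genes were added. The criteria of the tests of alternative explanations were set with the data already seen. Those comparing fibroblast with melanocyte markers, the within-group differences of cell cycle genes, dilution, and the short genes in the authors' deposited table were replaced after a first version had been run. The first version ruled out the general loss of keratinocyte RNA on melanocyte markers, and the second left it open on them. The third added immune, endothelial and muscle markers under the same rule. It argued against the general loss only if those markers came from such cells. The first version of the within-group test ruled out further differentiation for the S phase genes. The first version of the dilution test, on junction genes alone, ruled out dilution for them. The limit of 5 on mean normalized signal was set with the 4 genes' values known.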

Results

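RNA was sequenced from primary epidermal keratinocytes of newborn mice, cultured at passage 0 in low-calcium medium on a layer of growth-arrested J2-3T3 fibroblasts, a mouse feeder line that was taken off before RNA extraction. There were 2 control libraries and 2 Ovol2-deficient libraries. Expression was given as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for 24487 rows. Total counts per library were not in the files used here. From the steps between the lowest values in the authors' deposited table, and assuming equal normalized totals, the libraries held about 12400000 and 12700000 counted reads (control 1 and 2) and about 14800000 and 13500000 (Ovol2-deficient 1 and 2). Across 11350 genes with a mean FPKM of at least 1, log2(FPKM + 1) correlated at Pearson r = 0.986 between the controls, 0.987 between the deficient libraries, and 0.972 to 0.981 between the groups. These are correlations across genes, which are not independent replicates. The first principal component, with 54.9% of the variance, separated the groups. The second, with 27.6%, separated library 1 from library 2 in both groups.

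The comparison asks how gene expression in newborn keratinocytes differs when Ovol2, a zinc-finger transcription factor of epithelia, is deficient. Ovol2 (ENSMUSG00000037279.13, mm10, chromosome 2, 144305175 to 144332146, minus strand) stood at FPKM 2.68 and 2.14 in the controls and 1.45 and 0.94 in the deficient libraries. The means were 2.41 ± 0.385 and 1.20 ± 0.363 (SD, n = 2 per group), a log2 fold change of -0.64 with an SE of 0.18. Both deficient values lay below both control values, but the difference did not pass the test in limma (adjusted p = 0.129). In the authors' deposited table, whose log2 fold changes can lie nearer 0, that of Ovol2 was -0.36 with an adjusted p of 0.441. Which part of the gene was altered is not given in the sources used here, so reads outside it may count toward this level and it does not fully check the labels. Ovol1, the related family member, stood at 12.8 ± 2.37 in controls and 17.7 ± 4.46 in deficient libraries (log2 fold change 0.43, adjusted p = 0.296).

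In the Ovol2-deficient libraries, 19 of 44 measured genes of the G2 and M phases and 2 of 40 of the S phase fell. The Notch ligands Jag2 and Dll1 fell too, as did Lamb3, a laminin chain of the basement membrane. The late cornified envelope genes Lce1c, Lce1e, Lce1k and Lce3d rose. The growth factor genes Areg and Ereg rose, and so did the intermediate filament gene Vim. Of 22 measured markers of fibroblasts or feeder cells 4 rose as well, and bulk RNA cannot tell whether Vim rose in the keratinocytes. In all, limma called 153 of 11350 genes at an adjusted p under 0.05, 95 higher and 58 lower in the deficient libraries, with 29 of them changed at least 2-fold.

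**Figure D1:**
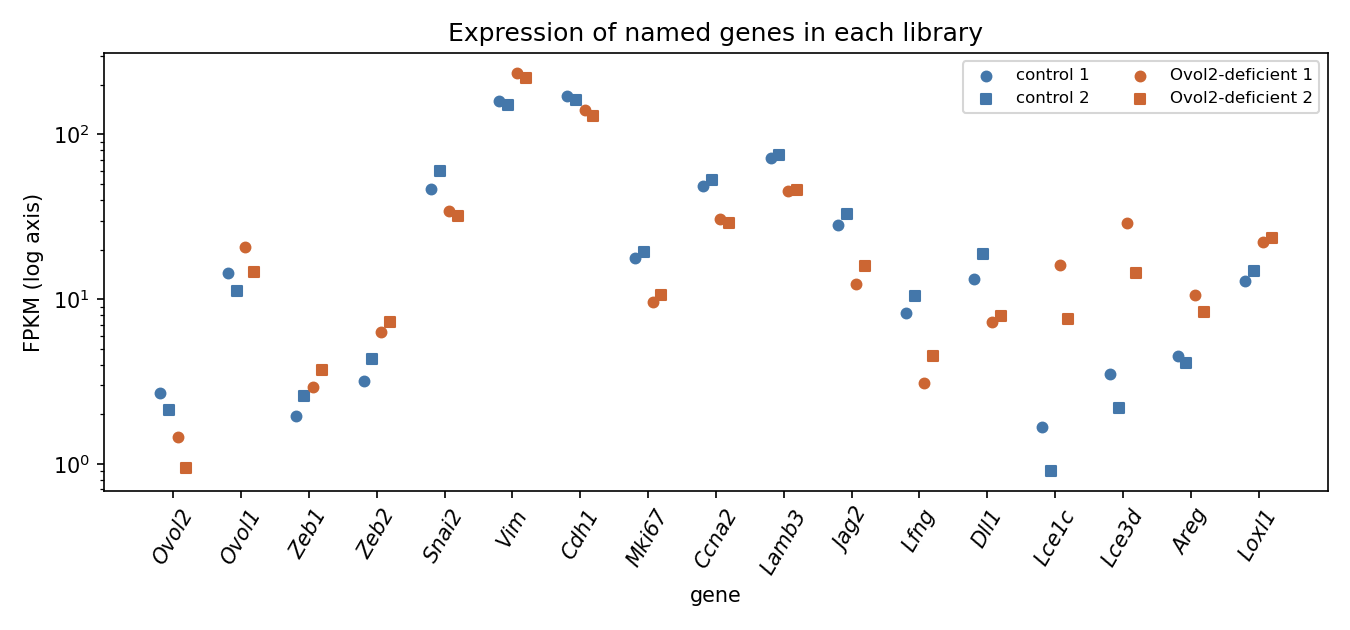
FPKM (log axis) of 17 named genes in each of the 4 libraries, blue for control and orange for Ovol2-deficient, with circles for library 1 and squares for library 2. Jag2 stood at 28.4 and 33.0 in the controls and 12.4 and 15.8 in the deficient libraries, and Lce3d at 3.49 and 2.18 against 29.1 and 14.5.

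Of 44 measured genes of the G2 and M phases, 19 fell, none rose and 25 did not pass the test over all genes. Adjusted over the list alone, 42 were called lower, and 42 had both deficient values below both controls. The list median was a log2 fold change of -0.64. Mki67, the proliferation marker, fell from 18.4 ± 1.11 to 10.1 ± 0.728 (log2 fold change -0.81, SE 0.10, adjusted p = 0.0353), and cyclin A2 (Ccna2) fell from 50.9 ± 2.65 to 29.8 ± 1.05 (log2 fold change -0.75, SE 0.09, adjusted p = 0.0353). The authors' deposited table called 37 of these genes lower. Of 40 measured S phase genes, 2 fell and 38 did not pass, with 29 called lower when adjusted over the list alone and all 40 below 0. Uhrf1, which maintains DNA methylation at replication, fell by 0.76 on the log2 scale (adjusted p = 0.0419), and Mcm6, a subunit of the replicative helicase, by 0.60 (adjusted p = 0.0482). Camera called both lists lower (adjusted p = 7.72e-34 for G2 and M, 2.83e-19 for S). With an estimated correlation neither passed (adjusted p = 0.338 for each). Without either deficient library no member of these lists was called, while the medians stayed at -0.56 to -0.70 for G2 and M and -0.36 to -0.49 for S.

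Among 19 measured basal keratinocyte genes 3 fell, 16 did not pass, and 9 were called lower adjusted over the list alone. Lamb3 fell from 73.6 ± 1.98 to 45.7 ± 0.660 (log2 fold change -0.68, SE 0.09, adjusted p = 0.0353). Dll1 fell as well, by 0.97 (adjusted p = 0.0470). The basal keratins did not pass, with Krt5 at 2861 ± 140 and 2376 ± 152 (adjusted p = 0.340) and Krt14 at 2259 ± 47.7 and 2027 ± 359 (adjusted p = 0.642), nor did the basal regulator Trp63 (log2 fold change -0.20, adjusted p = 0.348). Camera called the list lower (median -0.33, adjusted p = 2.23e-09; adjusted p = 0.338 with an estimated correlation). Without Ovol2-deficient library 1 none of its members was called, and without library 2 only 1 was.

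Of 15 measured Notch pathway genes, 3 fell and 12 did not pass; adjusted over the list alone, 3 were called lower and 2 higher. Besides Dll1, those that fell were the ligand Jag2 and Lfng, which modifies Notch receptors. Jag2 fell from 30.7 ± 3.24 to 14.1 ± 2.42 (log2 fold change -1.07, SE 0.14, adjusted p = 0.0353). Lfng fell from 9.33 ± 1.61 to 3.80 ± 1.001 (log2 fold change -1.11, SE 0.18, adjusted p = 0.0434). No member of the list was called under quantile normalization or in limma without its variance trend. With 1 library left out, log2 fold changes were -1.24 to -0.91 for Jag2, -1.33 to -0.90 for Lfng and -1.20 to -0.73 for Dll1. Camera did not call the list (median 0.06, mean -0.11, adjusted p = 0.646), but called it lower without control 2 (median -0.03, adjusted p = 0.0358). The other genes with the largest falls were Ctnnal1, Cyp2s1, Syce2, Clhc1 and Acpp, at log2 fold changes of -1.002, -0.98, -0.95, -0.95 and -0.92. In the Wnt list 1 of 20 measured genes fell, the ligand Wnt10a (log2 fold change -0.69, adjusted p = 0.0482), and camera called the list lower (median -0.14, adjusted p = 0.0110; adjusted p = 0.338 with an estimated correlation).

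Of 41 measured epidermal differentiation genes, 5 rose and 36 did not pass, 24 were called higher adjusted over the list alone, and the list median was 1.02. Lce3b rose from 0.639 ± 0.144 to 6.95 ± 2.36 (log2 fold change 2.25, SE 0.21, adjusted p = 0.0214) and Lce1c from 1.28 ± 0.544 to 11.8 ± 6.01 (log2 fold change 2.43, SE 0.32, adjusted p = 0.0353). Outside the list, Lce1e (2.62 to 21.6), Lce1k (0.452 to 8.44) and Lce3d (2.83 to 21.8) rose too, with adjusted p of 0.0392, 0.0353 and 0.0353. Lce1k stood at 0.378 and 0.526 in the controls and 12.0 and 4.86 in the deficient libraries. Without Ovol2-deficient library 1 none of these 4 passed (Lce1c adjusted p = 0.150, Lce1e 0.192, Lce1k 0.0563, Lce3d 0.123), nor did Lce1e without library 2 (0.102). The Lce genes are closely related copies in one cluster on chromosome 3, so the share of each is uncertain. The suprabasal keratins Krt1 and Krt10 overlapped between the groups, Krt10 at 23.2 and 3.85 in the controls and 43.9 and 19.6 in the deficient libraries (adjusted p = 0.331), and Krt1 at 9.71 and 1.77 against 17.8 and 6.9988 (adjusted p = 0.395). Both depended on the libraries: without control 1 they passed (Krt1 log2 fold change 2.14, adjusted p = 0.0207; Krt10 2.65, 0.00783), and the log2 fold changes of Krt1 and Krt10 were 1.17 and 1.49 with all libraries, 0.196 and 0.331 without control 2 and 0.554 and 0.927 without Ovol2-deficient library 1. The libraries of each group differed, with list medians of 0.28 and -0.28 in controls 1 and 2 and 1.38 and 0.55 in deficient libraries 1 and 2, relative to the control mean. Camera called the list higher (adjusted p = 2.04e-16; adjusted p = 0.462 with an estimated correlation). Without Ovol2-deficient library 1 none of its members was called, and without control 1 there were 25. The list median was 0.604 without control 2 and 0.601 without Ovol2-deficient library 1.

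Among 23 measured wound and stress genes of keratinocytes 4 rose and 19 did not pass. Adjusted over the list alone, 5 were called higher and 1 lower. The epidermal growth factor receptor ligands Areg and Ereg rose, Areg from 4.31 ± 0.303 to 9.51 ± 1.59 (log2 fold change 0.98, SE 0.14, adjusted p = 0.0392) and Ereg from 8.60 ± 0.295 to 15.9 ± 1.38 (log2 fold change 0.82, SE 0.11, adjusted p = 0.0353). Camera called the list higher (median 0.28, adjusted p = 0.00407; adjusted p = 0.592 with an estimated correlation), but not without control 2 (median 0.05, adjusted p = 0.0791). The median was 0.115 without Ovol2-deficient library 1 and 0.451 without library 2. Of 30 measured cyclin-dependent kinase inhibitors and p53 targets, Gadd45a rose (log2 fold change 0.58, adjusted p = 0.049994) and 29 did not pass, among them Cdkn1a at 279.8 ± 20.1 and 321.8 ± 29.6 (adjusted p = 0.419). Over that list alone 4 were called higher and 1 lower, and camera called it higher (median 0.14, adjusted p = 0.0136; adjusted p = 0.531 with an estimated correlation), but not without control 2 (adjusted p = 0.306). The median of that list was 0.233 without control 1 and 0.07 without Ovol2-deficient library 1.

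The list of transcription factors of the epithelial-mesenchymal transition (EMT) and mesenchymal genes had 20 measured members, of which 1 rose and 19 did not pass; adjusted over the list alone, 9 were called higher and 2 lower. Vim rose from 154.8 ± 6.62 to 229.2 ± 10.4 (log2 fold change 0.56, SE 0.09, adjusted p = 0.0473). Its log2 fold change was 0.52 to 0.61 with 1 library left out. Under quantile normalization Vim did not pass in limma (adjusted p = 0.0548). No member of the list was called there or in limma without its variance trend. Zeb2 (3.76 ± 0.780 and 6.79 ± 0.647, adjusted p = 0.0668), Zeb1 (log2 fold change 0.40, adjusted p = 0.264), Cdh2 (0.39, adjusted p = 0.132) and Fn1 (0.48, adjusted p = 0.134) did not pass in limma. Snai2 pointed the other way, at 53.2 ± 9.57 and 33.0 ± 1.76 (log2 fold change -0.66, adjusted p = 0.0608). With 1 library left out, the log2 fold change was 0.55 to 0.89 for Zeb2 and -0.84 to -0.48 for Snai2. The authors' deposited table gave adjusted p of 0.00174 for Zeb2, 0.0206 for Fn1 and 0.000564 for Snai2. Camera called the list higher (median 0.36, adjusted p = 0.00176; adjusted p = 0.338 with an estimated correlation), but not without Ovol2-deficient library 2 (adjusted p = 0.0621).

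Markers of other cell types moved in the same libraries. Of 22 measured fibroblast or feeder markers, 4 rose and 18 did not pass, and 20 were called higher and 1 lower adjusted over the list alone. The authors' deposited table called 14 of them higher. None was called under quantile normalization or in limma without its variance trend. The list median was 0.57 without Ovol2-deficient library 1 and 0.44 without library 2. With all libraries the median log2 fold change was 0.54, close to that of Vim, with an interquartile range of 0.45 to 0.57. The collagen-processing genes Loxl1 and Pcolce rose, from 13.8 ± 1.28 to 22.8 ± 0.898 (adjusted p = 0.0412) and from 45.7 ± 1.66 to 66.8 ± 1.80 (adjusted p = 0.0468). Of 9 measured melanocyte markers, 0 passed over all genes in limma (4 were called higher over the list alone), with a median of 0.36 and both deficient values above both controls for all 9. Camera called both lists higher (adjusted p = 4.34e-14 and 4.76e-05; adjusted p = 0.338 for each with an estimated correlation). Camera called none of the lists for immune (6 measured, adjusted p = 0.432), endothelial (3, adjusted p = 0.516), muscle (3, adjusted p = 0.654) or hair follicle cells (13, adjusted p = 0.750), though the immune list was called lower without control 1 (adjusted p = 0.0124).

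**Figure D2:**
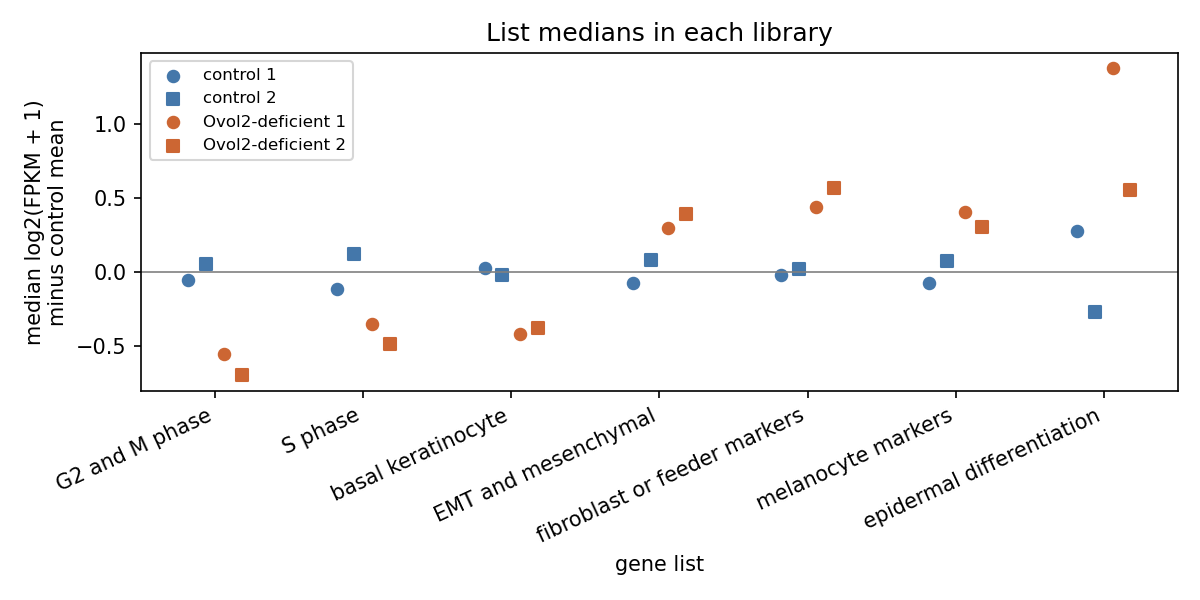
Median log2(FPKM + 1) of the measured genes of 7 lists in each of the 4 libraries, relative to the mean of the controls (blue for control, orange for Ovol2-deficient, circles for library 1 and squares for library 2). The fibroblast or feeder median was 0.44 and 0.57 in the deficient libraries and the G2 and M phase median was -0.56 and -0.70, while the differentiation median differed within each group.

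Epithelial junction and polarity genes had a small median difference, and 0 of 35 measured passed over all genes or over the list alone in limma. Single genes differed more, such as Cldn7 (log2 fold change -0.76) and Pard6b (-0.50). Both deficient values lay below both controls for 14 genes and above them for 2. The authors' deposited table called 3 lower and 0 higher. Cdh1, the epithelial cadherin, stood at 167.3 ± 6.89 and 135.8 ± 7.86 (log2 fold change -0.30, adjusted p = 0.167, and 0.0356 in the authors' deposited table) and Epcam at 17.8 ± 3.49 and 13.3 ± 0.0395 (adjusted p = 0.218; 0.0375 without control 1). Camera called the list lower (median -0.07, adjusted p = 0.0154; adjusted p = 0.712 with an estimated correlation), but not without Ovol2-deficient library 2 (median -0.006, adjusted p = 0.525); the median was -0.131 without control 2 and -0.154 without Ovol2-deficient library 1. Camera also called lower the lists of cholesterol and lipid synthesis (median -0.24, 11 of 30 lower over the list alone, adjusted p = 8.46e-08), cell migration and actin (-0.11, adjusted p = 0.0190) and planar polarity (-0.08, adjusted p = 0.0296), and called higher the interferon response list (0.26, 4 of 15 higher over the list alone, adjusted p = 0.000666). With an estimated correlation each of these had an adjusted p of 0.338. The migration and planar polarity calls were lost without control 2 (adjusted p = 0.143 and 0.0868) or Ovol2-deficient library 1 (0.173 for each), and that of migration without control 1 (0.0647). The interferon median was 0.406 without control 2, and the planar polarity median -0.145 without control 1. Camera did not call the lists of epithelial transcription and splicing regulators (median -0.02, mean 0.07, adjusted p = 0.951), TGF-beta and BMP response (adjusted p = 0.948), glycolysis and hypoxia (adjusted p = 0.560) or immediate early and dissociation stress genes (median 0.20, adjusted p = 0.0945). The last list was called higher without control 1 (median 0.36, adjusted p = 2.05e-06) and without Ovol2-deficient library 2 (0.265, adjusted p = 0.0120), and stood at -0.05 without control 2 (adjusted p = 0.627).

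**Figure D3:**
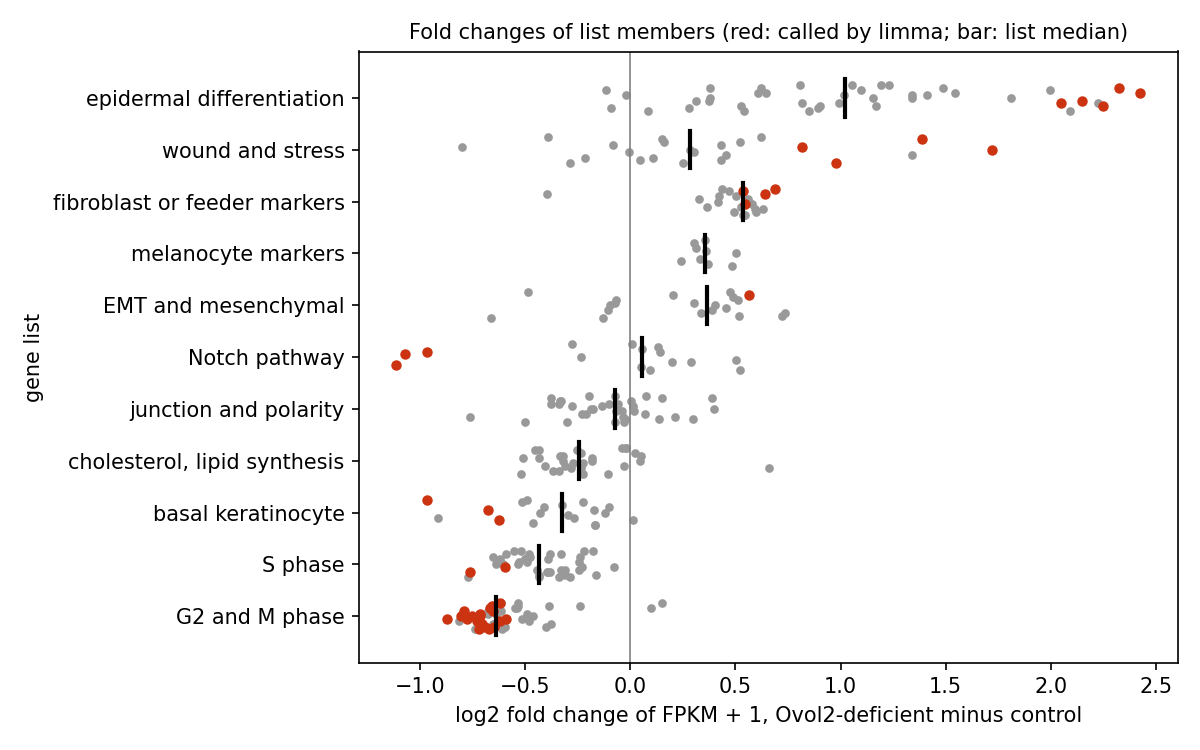
Log2 fold change of FPKM + 1 (Ovol2-deficient minus control) for each measured gene of 11 lists, with red points for genes called by limma over all genes, grey points for the others and a black bar at the list median. The G2 and M phase list, with a median of -0.64, has 19 red points, and the differentiation list, with a median of 1.02, has 5.

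Among the 153 called genes, the largest log2 fold changes were of Snora28, Snora15 and Mir8112, which were listed at 0 in both controls and at 151.1 and 116.3, 86.5 and 86.9, and 26.3 and 25.9 in the deficient libraries, and of Amd1, at 0.190 and 0.12985 against 12.8 and 23.8 (adjusted p of 1.15e-06, 4.47e-07, 3.53e-06 and 0.00227). In the authors' deposited table Snora28 had a log2 fold change of 0.06 (adjusted p = 0.973), while the other 3 had no adjusted p. Amd1 has a near-identical copy, Amd2, so its value is uncertain. The authors' deposited table called 513 genes, 270 higher and 243 lower. Of these, 508 were tested here and 136 were among the 153 calls, all in the same direction, as may be expected of 2 analyses of the same 4 libraries.

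The count of calls moved with the libraries used, to 10 without Ovol2-deficient library 1, 40 without library 2, 466 without control 1 and 237 without control 2, and to 5 with quantile normalization and 6 in limma without its variance trend. The labels do not say that the libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical.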

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

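Of the 15 lists called by camera, 14 stayed called without control 1, 11 without control 2 and 13 without either Ovol2-deficient library. The other fits kept all 15 (12 to 16 called in all, some new). Limma without the trend left camera unchanged and is no check. With an estimated correlation or with fry, 0 passed (1 and 8 at an unadjusted p under 0.05). The Ovol2 log2 fold change stayed negative and uncalled in every fit that tested it (-0.97 to -0.47, adjusted p 0.064 to 0.501). The G2 and M phase, S phase and epidermal differentiation lists had estimated correlations of 0.534, 0.552 and 0.847, far above the preset 0.01. Their very small adjusted p in camera rest on that preset. Lists with an estimated correlation below it lost their calls too, such as basal keratinocyte (-0.00744) and Wnt (-0.0378). With 4 libraries that test has few degrees of freedom. Its losses neither show nor exclude that correlation between genes made the calls. Fry for changes in either direction passed 12 lists at an adjusted p under 0.05. The 153 gene calls (95 higher, 58 lower) were far less stable. With the replicate block there were 518 (335 and 183). The numbers are not known to pair the libraries, and the correlation of same-numbered deviations was 0.22, in 2 mirrored pairs. The second principal component (27.6% of the variance) split library 1 (14.5 in control, 8.95 in deficient) from library 2 (-9.85 and -13.6). The third (17.6%) set control 1 and deficient 2 apart from the others. Limma called 5 genes between the numbers and 0 for that crossed split. An effect shared by same-numbered libraries stays open, and the main fit had no term for it. Quantile normalization left 5 gene calls (5 and 0). Under it 2056 genes had an unadjusted p under 0.05 in limma, against 1978. The 2-fold threshold, on the log2(FPKM + 1) scale, left 29 (26 and 3). A pseudocount of 0.1 gave 171. With no filter there were 192 calls, of which only 9 were among the 153. Leaving out 1 library gave 10 to 466 calls (10 to 298 higher, 0 to 168 lower), the lone library of a group being assumed to vary like the other group. The replicate block also called Krt1 (adjusted p = 0.0208), Krt10 (0.0271), Zeb2 (0.028), Snai2 (0.0358), Fn1 (0.0272) and 29 of 41 differentiation genes in place of 5, 32 of 44 G2 and M phase genes in place of 19, and 8 of 40 S phase genes in place of 2. The immediate early list was called with it (adjusted p = 0.0327) and the muscle list with no filter (0.0356). Of the 153, 145 were kept without control 1, 119 without control 2, 4 without Ovol2-deficient library 1 and 18 without library 2. All 153 kept their direction wherever tested. This was partly fixed in advance, since the replicate block leaves each fold change as it was. Leaving out 1 library also cannot reverse a gene without overlap between the groups.

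The following were chosen after seeing the data. Leaving out only all-zero genes left 3 (3 and 0; 2435 at an unadjusted p under 0.05). A mean FPKM of at least 5 gave 267 (152 and 115), median-ratio scaling 82 (51 and 31), limma without the trend 6 (6 and 0; 1976 at an unadjusted p under 0.05), and leaving out snoRNA, microRNA and Amd genes 255 (146 and 109). The authors' deposited table called 513. Among named genes, Krt5 went from -0.27 to 0 under quantile normalization, since it ranked first in all 4 libraries. Krt14 turned to 0.0668 there and ranged from -0.349 to 0.0139 with 1 library left out, the latter without Ovol2-deficient library 2; the cause was not tested. The other count-based alternatives planned (other size factors, upper quartile scaling, DESeq2, voom and count filters) were not run, since the files held no counts.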

Other observations

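The tests of explanations in this part were chosen after the results were seen, and the gene families below were picked by symbol after the data had been examined, while the calls and medians of the lists were planned. Of 19 measured Lce genes 10 rose and all 19 had a positive log2 fold change (median 2.22, camera adjusted p = 1.52e-20; adjusted p = 0.335 with an estimated correlation). Of 12 Sprr genes, also of the cornified envelope, 4 rose (median 1.10; adjusted p = 0.371 with an estimated correlation). Among 16 chemokines Ccl2 and Ccl7 rose, and 2 of 3 proliferin genes (Prl2c2 and Prl2c3) did (adjusted p = 0.335 with an estimated correlation for both families).

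The median of the fibroblast and feeder markers, 4 of 22 called higher, stood higher in both deficient libraries (0.54), and the EMT list, of which 1 of 20 members was called higher, had a median of 0.36. A larger share of fibroblast or feeder RNA is a candidate explanation, since 18 of 19 abundant markers (94.7%) lay within 2 SE of one common shift of 0.54, the exception being Fbln1 at -0.39. A general loss of keratinocyte RNA would raise the markers of every other cell type alike. The 5 abundant immune, endothelial and muscle markers (Lyz2, Cd68, Egfl7, Tnni2 and Acta2) did not follow. The fibroblast median log2 ratio lay 0.588 above theirs. The gap was 0.463 and 0.724 in the deficient libraries against 0.036 and -0.036 in the controls. Only 6 of 22 listed immune, 3 of 16 endothelial and 3 of 18 muscle markers were measured. The values argue against a general loss only if these 5 genes came from such cells, which bulk RNA cannot show. Melanocyte markers lay only 0.161 below the fibroblast markers, with overlapping gaps (0.036 and 0.248 against 0.067 and -0.067), so a larger share of both these cell types stays open. A rise of mesenchymal genes within the keratinocytes, as Ovol2 deficiency may bring, stays open, as 0 of 20 members of the EMT list exceeded the fibroblast median by more than 2 SE, and bulk RNA cannot place a transcript in a cell.

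Of 44 G2 and M phase genes 19 fell, and of 40 S phase genes 2 fell, in the deficient libraries. Dilution of keratinocyte RNA by RNA of other cells would lower keratinocyte genes by the same amount. The junction list (median -0.07) lay 0.566 and the basal keratinocyte list (-0.33) 0.312 above the G2 and M phase list, each beyond the interquartile ranges, which argues against it as the whole cause for that list. For the S phase list it stays open, since the junction list lay 0.361 above but the basal list only 0.107, within its interquartile range (-0.54 to -0.31). Cultures further along in differentiation would have both groups move together: between the libraries of a group, differentiation genes differed by 0.55 and 0.69 (library 1 minus 2, control and deficient). For G2 and M phase genes the ratio seen between groups predicts -0.35 and -0.43, and -0.11 and 0.11 were observed. This was at most 0.316 of the prediction, on 1 difference per group. The labels do not say that the libraries of a group came from separate cultures, so these differences cannot decide the question. For S phase genes the prediction was met in the controls (-0.24 observed, 1.01 of the prediction) and not in the deficient pair (0.13 against -0.29). Further differentiation stays open for both lists, as does an effect of the genotype on proliferation, which was not tested separately.

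Snora28, Snora15, Mir8112 and Amd1 were at or near 0 in both controls and high in both deficient libraries, and no gene showed the opposite at an FPKM of 5 (3 against 0 genes). FPKM estimation for short, embedded or near-identical genes, in place of a change in reads, is a candidate explanation for Snora28 and Mir8112, the 2 with a mean normalized signal of at least 5 in the authors' deposited table (50.4 and 9.13), where their smallest unadjusted p was 0.640 and their log2 fold changes 0.06 and -0.06. Snora15 and Amd1 had too few reads there to be tested (0.740 and 0.225), and 3 of the 4 genes had no adjusted p. The near-identical Amd2 moved against Amd1, from 99.2 and 99.1 to 66.4 and 51.5, so that their sum was 99.4 and 99.3 in the controls and 79.2 and 75.3 in the deficient libraries. For Snora28 and Mir8112, limma's log2 fold changes of 7.06 and 4.76 stood against unadjusted p of 0.755 and 0.640 in the authors' deposited table. This argues against a rise of the listed size in the counted reads of these 2 genes. A smaller change of them, and any biological change of Snora15 and Amd1, stays open and was not tested.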
